A study of Homo sapiens with 3 samples.

How the data were processed

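RNA from HEK293T cells was sequenced as 3 libraries, 1 per group: cells without overexpression (control), cells overexpressing ADAR2, and cells overexpressing both ADAR2 and SRSF9. Per the labels' protocols, RNA was purified with Trizol and libraries were made from total RNA with a NEBNext Ultra Directional kit. How messenger RNA was enriched is not stated there. The submitters' processing notes name the genome build hg19 and the tools STAR, Picard, GATK and SAMtools, without roles or versions. The program that counted reads per gene and its strand setting are not given in the sources used here. The authors deposited whole-number read counts per gene, not normalised, for 57268 gene identifiers with their symbols. Each library's column was matched to its labels by the library code given there. Because counting by strand is not stated, reads of overlapping and antisense genes may be mixed, and reads of near-identical copies may be split between them. The table holds reads per gene, so the planned comparison of editing levels per site was not run.

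Total counts were 152878282 for the control, 132887974 for the ADAR2 library and 97875935 for the library with both proteins. Library sizes were scaled by TMM (edgeR 4.0.16 in R 4.3.3), with factors of 1.01, 1.01 and 0.979, and levels are given as CPM, the counts divided by the scaled library size in units of 1e6 reads. The other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures. A log2 ratio between 2 libraries was taken after adding a prior count of 0.5, scaled to library size. Its 95% counting interval came from the exact Clopper-Pearson interval of one library's share of the reads of both. These intervals cover counting error only. With 1 library per group there is no replicate check of any difference, and no p-value is given. A gene was counted as 2-fold apart when its mean CPM over the 3 libraries was 1 or more (16072 genes), its ratio was 2-fold or more in either direction and its counting interval excluded 1. The limit that 3 counts set is 0.0194 CPM in the control, 0.0223 CPM in the ADAR2 library and 0.0313 CPM in the library with both proteins.

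Gene types, transcript lengths and GC content came from GENCODE v29 on GRCh38, matched on the identifier without its version. It held 51802 of the identifiers, and 469 of the 16072 genes had no match. That build is not the authors', so no coordinates are given. The following choices were made before the data were examined: the comparisons, the 30 gene lists, the rule for named genes and the other settings tried, apart from those said below to be later. A list's median log2 ratio over its measured members (mean CPM of 1 or more) was placed among 10000 random lists of the same size, matched on mean CPM in 20 equal-number bins. This percentile describes these libraries only, and genes are not replicates. The lists were ADAR family, SR and SR-related splicing factors, hnRNP proteins, core spliceosome, genes with known editing sites, reported modulators of editing, genes with Alu-rich untranslated regions, interferon-stimulated genes, NF-kB and inflammatory genes, immediate-early genes, unfolded protein and integrated stress response, heat shock and chaperones, oxidative stress response, p53 targets, DNA replication, mitosis, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, nonsense-mediated decay targets with snoRNA hosts, nuclear long noncoding RNAs, KRAB zinc finger genes, neuronal genes, HEK293 identity genes, and markers of fibroblasts, blood and other epithelial lines.

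Named genes are ADARB1, SRSF9, ADAR and ADARB2, then the 10 highest and 10 lowest log2 ratios per comparison among genes with mean CPM of 10 or more and a counting interval that excludes 1. Clone-based names, pseudogenes and RNAs under 200 nt were passed over where the reference identifies them. From each list described, members at 1.5-fold or more are named, or else the member with the largest ratio. Genes named outside this rule are said to be so.

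The other settings tried were DESeq2 1.42.0 size factors, plain library totals, upper-quartile scaling, library sizes without mitochondrial genes, ADARB1 and SRSF9, no filter on low counts, a mean CPM of 10, a prior count of 5, a 1.5-fold threshold, an interval wholly beyond 2-fold, protein-coding genes alone, a mean in place of the median for lists, and 10 expression bins. After the data were seen, removal of a trend with GC content and random lists from protein-coding genes were added. The trend was the median log2 ratio in 50 equal-number bins of the longest transcript's GC content over 9592 protein-coding genes with mean CPM of 10 or more, smoothed over 5 bins.

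The calculation was tested on simulated Poisson counts for the 16072 genes of each comparison. All 67 genes set at 2.5-fold were recovered for ADAR2 against control and for both proteins against control, and 66 of 67 for both proteins against ADAR2. All 66 genes set at 4-fold were recovered in each of the 3 comparisons, and 0 of 15872 unchanged genes were called in each. Of the 67 genes set at 1.5-fold, below the threshold for a call, 0 were called in each. These simulated counts hold counting error only, so they do not test calls that arise from other differences between libraries.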

Results

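Transcript levels were measured by RNA sequencing in HEK293T cells, a human embryonic kidney line, as 3 libraries with 1 library per group. The control carried no overexpression, the second library came from cells overexpressing ADAR2, and the third from cells overexpressing ADAR2 together with SRSF9. ADAR2, encoded by ADARB1, deaminates adenosine to inosine in double-stranded RNA. SRSF9 is a serine/arginine-rich splicing factor. The study asked how SRSF9 affects editing at sites specific to ADAR2. The values analysed here are read counts per gene, so they describe transcript levels and not editing levels. Reads were counted over 35910 genes in the control, 34647 in the ADAR2 library and 34040 in the library with both proteins, from totals of 152878282, 132887974 and 97875935 reads.

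Both overexpressed genes followed the labels. ADARB1 (ENSG00000197381.11) had 17547 reads in the control, 2161556 in the ADAR2 library and 1308303 in the library with both proteins. These correspond to 113.6, 16100.0 and 13647 CPM. The ADAR2 library thus held 142 times the control level (95% counting interval 139.7 to 143.9). SRSF9 (ENSG00000111786.4) stood at 372 CPM in the control and 369 CPM in the ADAR2 library, a ratio of 0.991 (0.979 to 1.003). With both proteins it reached 18288 CPM, 49.6 times the ADAR2 library (49.1 to 50.003). ADARB1 was at 0.848 times its ADAR2 level in that library (0.846 to 0.849), so the transcript of the editing enzyme was not at equal level in the 2 overexpressing libraries. ADAR, which encodes the other catalytically active deaminase of this family, was at 235, 231 and 224 CPM. ADARB2, the brain-enriched family member, had 0, 1 and 0 reads, below the floor of 3 reads in each library. Reads of the plasmids and of the resident genes were not separated.

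**Figure D1:**
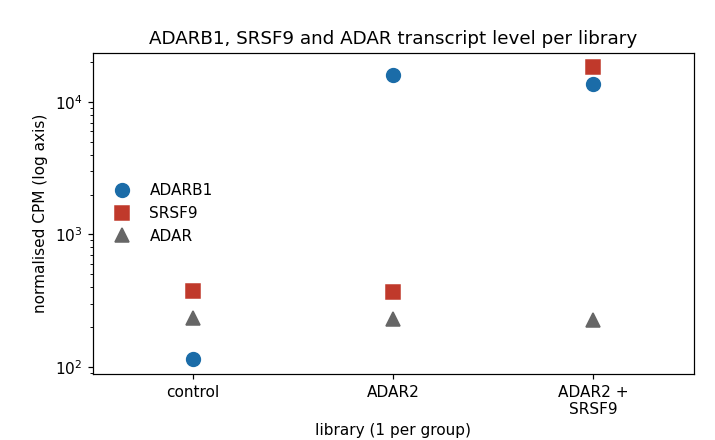
Normalised CPM (log axis) of ADARB1, SRSF9 and ADAR in the control, the ADAR2 library and the library with ADAR2 and SRSF9, 1 point per library. ADARB1 goes from 113.6 CPM in the control to 16100.0 and 13647 CPM, SRSF9 reaches 18288 CPM in the last library, and ADAR lies between 224 and 235 CPM.

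The log2 ratios against the control followed the GC content of the transcript. Across 10198 genes with mean CPM of 10 or more, Spearman's rho between log2 ratio and GC content was 0.76 for ADAR2 against control, 0.70 for both proteins against control and 0.19 for both proteins against ADAR2. These are correlations across genes, which are not independent replicates. In the lowest decile of GC content (median 36.8%) the median log2 ratio of ADAR2 against control was -0.17, and in the highest (median 63.8%) it was 0.18. Counting error was small beside such differences: 76.3% of the 10362 genes at this level had a counting interval that excluded 1 in ADAR2 against control, 55.3% in both proteins against ADAR2 and 77.7% in both proteins against control. An interval that excludes 1 therefore compares 2 libraries, not 2 conditions.

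**Figure D2:**
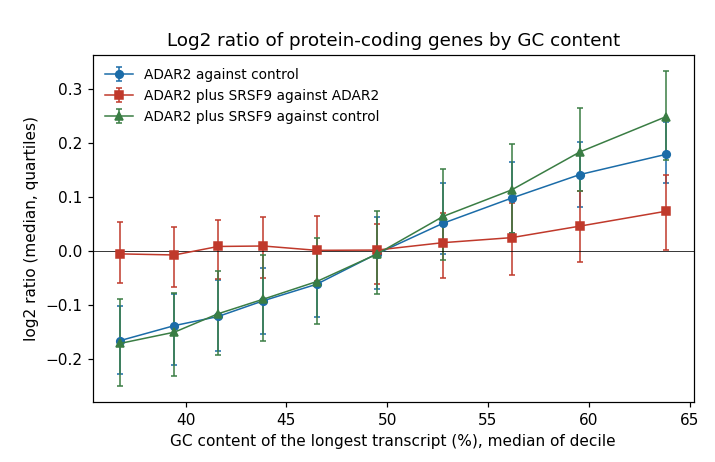
Log2 ratio (median, with quartiles as bars) of protein-coding genes with mean CPM of 10 or more in deciles of GC content of the longest transcript, for the 3 comparisons. From the lowest to the highest decile the median goes from -0.17 to 0.18 for ADAR2 against control, from -0.17 to 0.25 for both proteins against control and from -0.01 to 0.07 for both proteins against ADAR2.

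The first comparison asked what ADAR2 overexpression went with at the transcript level. Besides ADARB1, the gene furthest above the control was HSPA6, a stress-inducible member of the HSP70 chaperones, with 158 reads in the control and 1947 in the ADAR2 library. It was 14.1 times higher (12.1 to 16.8). The other 9 of the 10 highest named genes were 1.36 to 1.49 times the control level: FBXL19-AS1, an antisense RNA, YPEL3, the homeobox gene HOXB4, ARPC4, a subunit of the actin-nucleating Arp2/3 complex, ZDHHC11, TMEM175, the transcription factor ZBTB7B, the ubiquitin ligase MIB2 and the claudin CLDN15. GC content of the 10 transcripts ran from 52.6% to 68.4%, and HSPA6 alone of them was at 1.5-fold or more, with the GC trend kept and with it removed. The lowest was RN7SK, the noncoding RNA of the 7SK particle that holds back transcription elongation, at 0.0848 times the control level (0.0742 to 0.0962), with 3438 reads in the control and 253 in the ADAR2 library. The row with the symbol MIR663A, whose identifier the reference lists as a processed transcript, was at 0.470 times (0.445 to 0.496), and ANKRD30BL at 0.478 times (0.443 to 0.514). The remaining 7 lay between 0.670 and 0.703 times: C10orf118, the histone demethylase gene KDM5B, LIN7A, the golgin GOLGA4, JMJD1C, the sugar transporter gene SLC2A13 and UTP14C, an intronless copy of UTP14A whose reads can be shared with it. Among higher genes 2 clone-based names were passed over, and 5 among lower genes.

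In all, 45 of the 16072 genes were at least 2-fold apart, 11 higher and 34 lower in the ADAR2 library. Most were weakly expressed: 2 higher and 7 lower genes had a mean CPM of 10 or more. At 1.5-fold the numbers were near equal, with 100 higher and 103 lower. Of the 45, 19 were protein-coding, 6 higher and 13 lower. No replicate supports any of these differences, and effects of ADAR2 cannot be told apart here from those of overexpression itself.

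Of the 30 gene lists, 5 had a median outside the central 95% of matched random lists, where 1.5 lie there by chance if lists are independent. The 42 mitosis genes had a median log2 ratio of -0.16, below each of the 10000 random lists, with 0 members at 1.5-fold. TOP2A, the topoisomerase of chromosome segregation, was lowest at -0.46. This list was AT-rich (median GC content 43.2%), and with the GC trend removed its median was -0.10, again below each random list. The 15 measured replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median of -0.21 (percentile 0.03) and 4 members lower by 1.5-fold: HIST1H4E (-1.22), HIST1H2AC (-0.86), HIST1H2BD (-0.64) and HIST1H2BJ (-0.59). Their GC check covered the 10 of 15 with a GC value (median -0.34, percentile 0), so it does not speak for the whole list. With the fewer members at a mean CPM of 10 or more the list was inside the range (percentile 4.29). The 26 p53 targets had a median of 0.15 (percentile 99.98) and 0 members at 1.5-fold, with GDF15, a secreted stress factor, highest at 0.49. With the GC trend removed the median was 0.08 (percentile 99.9). Nuclear long noncoding RNAs and paraspeckle genes (12 measured) had a median of -0.12 (percentile 1.48), with NEAT1, the scaffold of paraspeckles, lowest at -0.32. With the GC trend removed this median was -0.02 at percentile 37.3. The ADAR family list (5 measured, ADARB1 itself among them) had a median of 0.16 at percentile 97.98, and was inside the range with members at a mean CPM of 10 or more (82.9) and with 10 expression bins (97.2). The long noncoding list was inside it with a mean over members (3.97).

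For stress genes in the ADAR2 library the answer depended on the setting. The heat shock list (23 measured) had a median of 0.01 at percentile 69.4, with HSPA6 the 1 member at 1.5-fold. The unfolded protein and integrated stress response list (39 measured) had a median of 0.04 at percentile 95.2, with 2 members at 1.5-fold: CHAC1, a glutathione-degrading enzyme (log2 0.67), and DDIT3, the transcription factor CHOP (0.65). Both lists lay above the range with the GC trend removed (heat shock 0.04 at percentile 99.2, stress response 0.04 at percentile 99.4) and with a mean over members (percentiles 98.4 and 98.7), where the heat shock mean of 0.20 includes HSPA6.

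**Figure D3:**
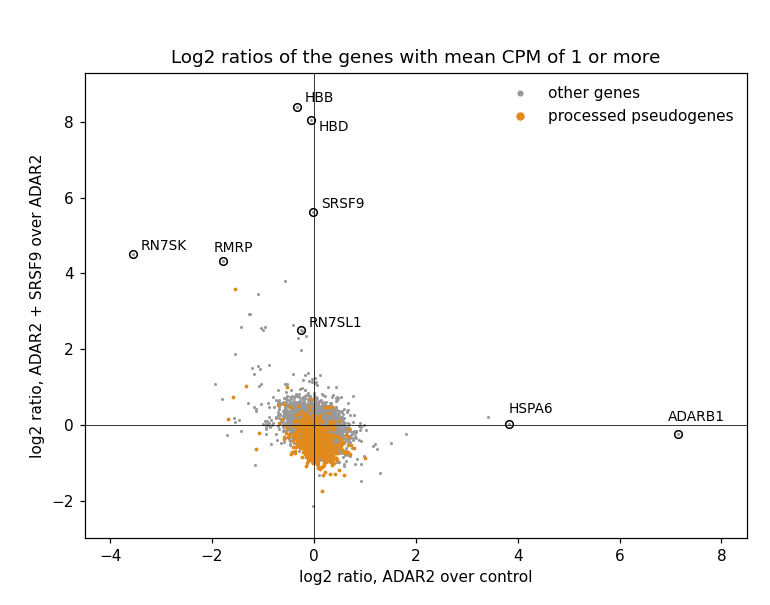
Log2 ratio of both proteins over ADAR2 (y axis) against log2 ratio of ADAR2 over control (x axis) for the 16072 genes with mean CPM of 1 or more, processed pseudogenes in orange. HBB (8.38) and HBD (8.06) stand at the top with SRSF9 (5.63), RN7SK lies at -3.56 and 4.52, and HSPA6 at 3.82 and 0.02.

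The second comparison set both proteins against ADAR2 alone, the contrast that differs by SRSF9 in this design. The largest differences besides SRSF9 were those of the beta-type globin genes HBB and HBD, which encode the oxygen-carrying subunits of adult haemoglobins. HBB had 154 reads in the ADAR2 library and 36744 with both proteins, 333 times higher (285.3 to 394.0). HBD had 476 and 90665 reads, 266 times higher (243.8 to 292.5). The 2 genes are close copies, so how reads divide between them is uncertain. RN7SK was 22.9 times higher (20.2 to 26.2) and RN7SL1 and RN7SL2, near-identical genes of the signal recognition particle RNA, 5.62 and 5.58 times. MIR663A was 2.95 times higher (2.79 to 3.12) and ANKRD30BL 2.77 times (2.57 to 2.997). Their reads ran in parallel over control, ADAR2 and both proteins, at 4566, 1864 and 3927 against 2396, 994 and 1969. Whether the 2 rows share reads was not tested. The small cytoplasmic RNA BCYRN1, SNHG11, a snoRNA host, and the initiation factor gene EIF4A1, which overlaps a readthrough gene, were 1.55, 1.53 and 1.49 times higher. RN7SK, MIR663A and ANKRD30BL were below the control in the ADAR2 library, which enters both comparisons with opposite sign.

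Lowest among named genes was RSPO1, a secreted activator of Wnt signalling, at 0.539 times the ADAR2 level (0.501 to 0.580). CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, was at 0.617 times (0.593 to 0.642). Then came MTRNR2L12 (0.618), PABPC3 (0.652), MTRNR2L8 (0.659), MSL2 (0.686), ZNF467 (0.698), MIR4426 (0.730), RPL9P8 (0.731) and KLHL11 (0.738). Several of these share sequence with other loci: the MTRNR2L genes are nuclear copies of mitochondrial ribosomal RNA and PABPC3 is an intronless copy of PABPC1. RPL9P8 bears a pseudogene name but had no match in the reference, and the identifier of the MIR4426 row is listed there as protein-coding. Among lower genes 57 clone-based names and 82 pseudogenes were passed over, and among higher genes 4 clone-based names and 1 RNA under 200 nt.

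Counted over all genes, 80 were at least 2-fold apart, 46 higher and 34 lower with both proteins. Of these, 19 were protein-coding, 10 higher and 9 lower. With a mean CPM of 10 or more there were 12 higher and 1 lower. At 1.5-fold the balance turned, with 140 higher and 405 lower. Processed pseudogenes, intronless copies of messenger RNAs, were lower as a class: the median log2 ratio of 1094 of them was -0.46 (95% interval of the median over genes -0.48 to -0.45), against 0.02 for 12765 protein-coding genes, and 23 of the 34 genes lower by 2-fold belonged to them. In ADAR2 against control their median was 0.03.

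Among the lists, 7 of 30 had a median outside the random range. The p53 targets were lowest, with a median of -0.18 below each of the random lists and 2 of 26 members lower by 1.5-fold, GDF15 (log2 ratio -0.99) and CDKN1A (-0.70). The ADAR2 library is the reference here, and the same list lay above the control in it. Mitosis genes had a median of -0.05 (percentile 0.00) and 0 of 42 members at 1.5-fold, CDC25C having the largest ratio (-0.24). The glycolysis and hypoxia list (33 measured) had a median of -0.05 at percentile 0.03, with the glucose transporter gene SLC2A3 at -0.37. Higher medians were small: 0.07 for hnRNP proteins (percentile 99.5), led by HNRNPU at 0.22, 0.06 for cholesterol and fatty acid synthesis (percentile 99.3), led by the lipogenic transcription factor gene SREBF1 at 0.22, and 0.08 for the oxidative stress response (percentile 99.3). In that last list 2 of 20 members were higher by 1.5-fold, the metallothionein genes MT1F (0.64) and MT1X (0.59). With the GC trend removed it was at percentile 97.4, inside the range. With a mean over members hnRNP proteins (89.9), cholesterol and fatty acid synthesis (95.1) and the oxidative stress response (95.6) were all inside it. Replication-dependent histones had a median of 0.16 (percentile 98.9) with 4 of 15 higher by 1.5-fold: HIST1H4E (2.82-fold), HIST1H4C (log2 ratio 1.23), HIST1H3B (0.86) and HIST1H4K (0.61). With members at a mean CPM of 10 or more the sign turned, to -0.0323, and with random lists from protein-coding genes the list was inside the range (96.9). In both proteins against control the histone median was -0.04 (percentile 30.3), inside the range. The ADAR2 library is the reference here too, and this list lay below the control in it.

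SR and SR-related genes other than SRSF9 and the genes of edited transcripts differed little between these libraries. Of 23 SR and SR-related genes SRSF9 alone was at 1.5-fold, and the list median was 0.03 at percentile 64.1. Of 35 measured genes with known editing sites, 0 were at 1.5-fold in each of the 3 comparisons, with medians of 0.02, 0.00 and 0.03. The largest ratio in both proteins against ADAR2 was that of CDK13 (-0.22). The genes with Alu-rich untranslated regions (26 measured) had a median of -0.03 (percentile 3.09, and 2.11, outside the range, with random lists from protein-coding genes), with MDM2 at -0.29, and the 25 reported modulators of editing a median of 0.02 (percentile 52.2), with AIMP2 at 0.13. In ADAR2 against control the modulators had a median of -0.09 (percentile 2.64). With 10 expression bins they were outside the range (2.355), and with the GC trend removed at percentile 44.4. In both proteins against control the Alu-rich genes had a median of -0.08 (percentile 6.66). They were outside the range with a mean over members (1.76), and at percentile 63.1 with the GC trend removed.

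The lists below had medians inside the random range in each of the 3 comparisons without a GC correction and with 20 expression bins. Medians are given here in the order ADAR2 against control, both against ADAR2, both against control. Medians were -0.02, 0.06 and 0.00 for interferon-stimulated genes (33 measured). ISG20, an exonuclease, was at a log2 ratio of 0.64 against the control and -0.75 with both proteins against ADAR2, where IFI27 was at 0.70. They were 0.02, 0.01 and 0.01 for NF-kB and inflammatory genes (9 measured), with RELB at -0.37 against the control, and 0.01, 0.03 and 0.01 for immediate-early genes (32 measured). Of the latter KLF2 was at 0.98 and then -0.83, and EGR2 at 0.75 with both proteins against ADAR2. ISG20 and KLF2 had opposite signs in the first 2 comparisons, which share the ADAR2 library. A difference in that library alone can give this, and cannot be told apart from a response with 1 library per group.

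Core spliceosome genes (40 measured) had medians of 0.00, 0.05 and 0.04, with PRPF6 at 0.29 against the control. In both proteins against ADAR2 their percentile was 97.3, with 33 of 40 above 0. It was 97.52, outside the range, with 10 expression bins, and 99.4 with the GC trend removed. DNA replication genes (42) had medians of -0.03, 0.02 and 0.01, with MCM5 at 0.36 in both proteins against control. Cytosolic ribosomal proteins (77) had -0.03, 0.04 and 0.01, with RPS10 at 0.38 in both proteins against ADAR2. Mitochondrially encoded genes (13) had medians of -0.08, 0.03 and -0.07, with MT-CYB at 0.23 in the last comparison, and nonsense-mediated decay targets with snoRNA hosts (26) 0.00, 0.03 and 0.00, with SNHG15 at 0.39. KRAB zinc finger genes (60) had medians of 0.00, -0.02 and 0.01, with ZNF441 at -0.59 in both proteins against ADAR2. With the GC trend removed the KRAB list was above the range in ADAR2 against control (0.12) and in both proteins against control (0.09), and with random lists from protein-coding genes it was below it in both proteins against ADAR2 (percentile 1.62). Neuronal genes (22) had 0.03, -0.01 and 0.02, with GAP43 at -0.81 and then 0.74, and HEK293 identity genes (22) -0.02, -0.01 and -0.03, with KRT19 at -0.73 in both proteins against ADAR2. Markers of other cells were few: fibroblasts (6) 0.03, -0.03 and 0.18, with ACTA2 at 0.71 against the control and COL6A3 at 0.64 in both proteins against ADAR2, blood (7) 0.05, 0.03 and 0.24, with HBB the 1 member at 1.5-fold, and other epithelial lines (5) -0.07, 0.08 and 0.04, with EPCAM at 0.20 in both proteins against ADAR2.

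**Figure D4:**
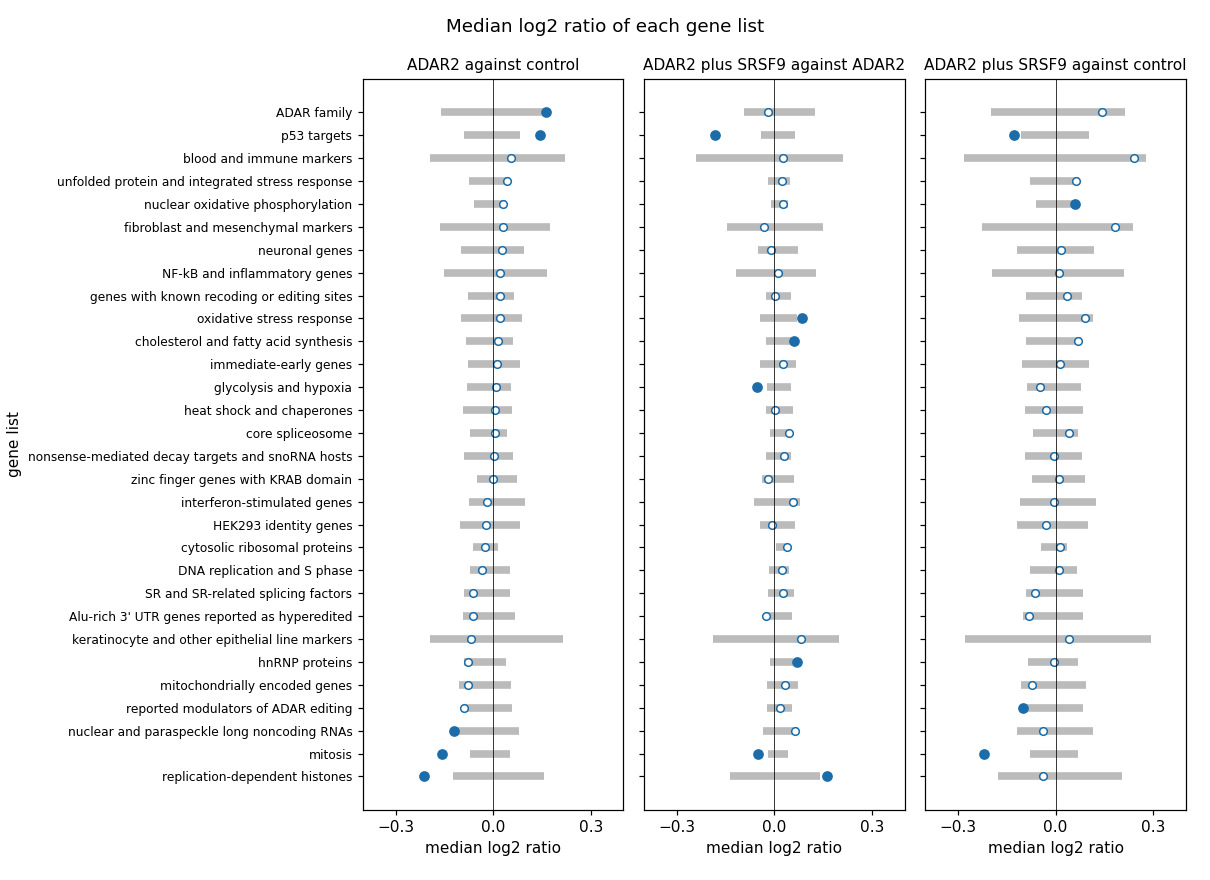
Median log2 ratio of each of the 30 gene lists (points) in the 3 comparisons, with the central 95% of 10000 random lists matched on expression (grey bars). Filled points lie outside the bar: 5 lists in ADAR2 against control, 7 in both proteins against ADAR2 and 4 in both proteins against control.

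The third comparison set both proteins against the control. HBB and HBD were again far higher, 266 (233.8 to 305.7) and 256 (236.1 to 278.8) times the control level. HSPA6 was 14.3 times higher (12.2 to 17.1), close to its ratio in the ADAR2 library. RN7SL2 and RN7SL1 were 4.78 and 4.72 times higher, RN7SK 1.94 times, SNHG11 1.63 times, VPS9D1-AS1 1.60 times, C14orf80 1.58 times and LINC00342 1.53 times. The lowest were MTRNR2L12 (0.589 times the control), MTRNR2L8 (0.619) and RSPO1 (0.623), then SGOL2, a protector of centromeric cohesion (0.643), TFPI, an inhibitor of the coagulation pathway (0.655), UTP14C, ZNF654, JMJD1C, RBM12B and C10orf118, the last 5 between 0.656 and 0.662. All 10 lower genes were at 1.5-fold, and 2 of them with the GC trend removed. Of the 10 higher genes 8 had a GC value, and 6 of these were at 1.5-fold with the trend removed. Passed over were 9 among higher and 25 among lower genes. At least 2-fold apart were 90 genes, 49 higher and 41 lower, of which 27 were protein-coding. With a mean CPM of 10 or more there were 11 higher and 0 lower, and at 1.5-fold 250 higher and 391 lower. Processed pseudogenes made up 23 of the 41 lower genes, and the median of the 1094 was -0.42, with 91.4% below 0. Among genes with a GC value, 40 were higher and 40 lower, and 33 and 43 with the GC trend removed.

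Of the lists, 4 lay outside the random range, and with a mean over members mitosis alone of these stayed outside, p53 targets going to percentile 3.50, modulators of editing to 9.55 and nuclear oxidative phosphorylation to 92.1. Mitosis genes had a median of -0.22, below each random list, with 0 of 42 at 1.5-fold and TOP2A at -0.54. Without the GC trend the median was -0.16. The p53 targets had a median of -0.13 (percentile 0.83), with GDF15 at -0.50, and the modulators of editing -0.10 (percentile 1.42), with TOP3B at 0.34 having the largest ratio. With the GC trend removed the modulators were at percentile 13.1. Nuclear oxidative phosphorylation genes (68 measured) had a median of 0.06 (percentile 97.86), NDUFA11 being highest at 0.46. With members at a mean CPM of 10 or more this list was at percentile 95.7, inside the range. With the GC trend removed its median was 0.07 at percentile 100, outside it. In the unfolded protein and integrated stress response list CHAC1 was the 1 member at 1.5-fold, at a log2 ratio of 1.25.

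Both overexpression libraries were compared with the same control library. Genes 2-fold apart in the same direction in both numbered 16, 5 higher and 11 lower, and 7 went in opposite directions. Independent lists would share 0.0335 higher and 0.0867 lower genes. ADARB1, 1 of the 5 higher genes, was overexpressed in both libraries by design, so it was bound to be shared. The 1 control library cannot be split, so genes shared in this way can come from it. The higher genes were ADARB1, HSPA6, its neighbour and close copy HSPA7, the integrin gene ITGB2 and MIR22HG, and the lower ones included TAF7L, PDZK1, ARHGAP30 and MGAM. Of these, HSPA7, ITGB2, MIR22HG and the 4 lower genes were chosen after their values were seen. Across 10360 genes with mean CPM of 10 or more, Pearson's r between the log2 ratios was 0.60, against 0.42 in the simulations, and the covariance was 0.0235 against 0.000428. The simulations hold counting error only. Over 10196 genes with a GC value r was 0.63 and the covariance 0.0241. With the GC trend removed r was 0.37, below the simulated r, and the covariance 0.00817, above the simulated 0.000428. Differences that the libraries do not share lower r and are absent from the simulations, so the values of r do not compare directly.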

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

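Removal of the GC trend and random lists from protein-coding genes were chosen after the data were seen. Under the 4 other scalings the number of genes 2-fold apart was 45 to 46 for ADAR2 against control, 80 to 85 for both proteins against ADAR2 and 90 to 99 for both proteins against control. With plain totals lower genes outnumbered higher ones in the last 2 comparisons, 42 higher and 43 lower, and 46 higher and 53 lower. Among genes with a GC value it was 39, 68 and 80, and 39, 69 and 76 with the GC trend removed. In the order ADAR2 against control, both against ADAR2, both against control, the count was 2648, 2676 and 3194 without a filter on low counts, 9, 13 and 11 with a mean CPM of 10, 203, 545 and 641 at 1.5-fold, 27, 34 and 40 with the interval wholly beyond 2-fold, and 19, 19 and 27 for protein-coding genes alone. These follow from fewer or more genes being admitted. The depth of these libraries leaves genes near 1 CPM the least certain.

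For lists, the number outside the random range in ADAR2 against control was 3 with a mean CPM of 10, for fewer members, and 10 with the GC trend removed. In both proteins against control it was 12 with the GC trend removed. Lists gained in this way were nuclear oxidative phosphorylation, heat shock and Alu-rich genes in the first of these, stress response, KRAB zinc finger and hnRNP genes in both, and ADAR family, SR, immediate-early, glycolysis and HEK293 identity genes in the last. Both numbers include histones, whose GC check covered 10 of the 15 measured members. The median of replication-dependent histones in both proteins against ADAR2 turned to -0.0323 with a mean CPM of 10. The cause of these shifts was not tested. No other list that lay outside the range before any change of setting changed sign. Of those gained with the GC trend removed, KRAB, hnRNP and Alu-rich genes changed sign in ADAR2 against control and hnRNP, SR and immediate-early genes in both proteins against control. The ADARB1 log2 ratio for both proteins against ADAR2 was -0.28 with plain totals and -0.25 with DESeq2 size factors, and 6.86 for both proteins against control with plain totals. SRSF9 was at 5.59 with plain totals and 5.62 with DESeq2 size factors against ADAR2, and 5.57 with plain totals against the control, each a shift by the scaling itself. Genes shared by both overexpression libraries numbered 80 at 1.5-fold, 34 higher and 46 lower, while 12 went in opposite directions. With a mean CPM of 10 or more 2 were shared, ADARB1 and HSPA6, and 4 went in opposite directions. Of the 60 ratios of the highest and lowest named genes 0 changed sign, while SRSF9 in ADAR2 against control, near 0, did with DESeq2 size factors, and the GC correction moved 29 of 55 values beyond their counting interval. Editing levels per site were not run, since the values are reads per gene. No paired analysis was possible because each group holds 1 library.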

Other observations

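The tests on globin genes, on GC content and parent genes of pseudogenes, and on RNAs without a poly(A) tail were chosen after the results were seen. The test on the placement of reads was fixed before its result was seen, and its repeat on the control library alone came after. The bound on the spread of RNAs without a poly(A) tail was replaced once, after that spread was known, by one from random lists, and the need for more than 1 library per group was added to the test of their response after its count was seen. All patterns below rest on 1 library per group, and each explanation is a hypothesis.

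HBB and HBD together stood at 5.13 CPM in the control, 4.69 CPM in the ADAR2 library and 1329 CPM in the library with both proteins. RNA from red blood cells would bring alpha-globin RNA at a similar level, yet HBA1 and HBA2 together reached 0.877% of HBB and HBD there, 11.7 CPM against 12.2 CPM in the ADAR2 library, which argues against it. A candidate explanation is beta-globin sequence carried in the DNA transfected for SRSF9, as many expression plasmids use a globin intron or polyadenylation site. The gain of HBB and HBD was 7.39% of the gain of SRSF9, which allows this but does not settle it without the plasmid sequence. A response of the locus to SRSF9 stays open too: HBE1, HBG1 and HBG2 summed were at 0.442 times the ADAR2 level (0.145 to 1.15), from 19 and 6 reads, too few to decide.

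Processed pseudogenes were lower with both proteins than with ADAR2 alone, with a median log2 ratio of -0.46. The GC trend was fitted on protein-coding genes, so a GC effect particular to pseudogenes was not tested. From the lowest to the highest decile its median went from -0.01 to 0.07. That trend is too small to account for the lower level: the median was -0.47 with it removed (-0.49 to -0.46). Lower parent genes do not either: over 579 pseudogenes whose parent gene could be named, the median difference from the parent was -0.52 (-0.54 to -0.49), and the median of the 274 parents was 0.04. Another placement of reads between parents and copies, for example from reads of another length or quality, may explain it, a response to SRSF9 being untested: the 193 pseudogenes with the highest parent level relative to their own stood below the 193 with the lowest, a difference of medians of -0.21 (-0.55 against -0.34, with intervals apart). Because that split uses levels that include the lower library, part of it could be built in, yet with the split made on the control library alone the difference was also -0.21 (-0.54 against -0.33). The intervals in these comparisons take pseudogenes as independent, although the 579 come from 274 parents, so they may be too narrow.

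Several RNAs that lack a poly(A) tail were lower in the ADAR2 library and higher with both proteins. Of 41 such RNAs listed for this purpose 15 were measured, with medians of -0.25 in ADAR2 against control, 2.48 in both proteins against ADAR2 and 1.51 in both proteins against control. Of the 15, 11 were lower in the first and higher in the second, a count that the ADAR2 library favours by entering both ratios with opposite sign and that includes near-identical copies sharing reads (RN7SL, RNU1 and SNORD3 genes). The listed RNAs did not move by a common amount in ADAR2 against control, with RN7SK at -3.56, RMRP at -1.78 and RN7SL1 at -0.25. Their interquartile range was 0.96, where the central 95% of random lists matched on expression ended at 0.406. That bound was set after the spread was known, so it is no test of a common change in yield during library preparation. The spread in both proteins against ADAR2 was not examined in this way. Yields that differ between RNAs, and a response to ADAR2 or SRSF9, cannot be told apart with 1 library per group.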
